A study of Mus musculus with 40 samples.

How the data were processed

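RNA from mouse bone was measured on 40 arrays of 5 Illumina BeadChips, slides that carry 8 arrays each and are read in 1 colour. Per the labels, the mice were 15-week-old C57BL/6 females, wild type or lacking activation function 1 (AF-1) of estrogen receptor alpha (ERα). Per the labels, they were ovariectomized and 1 week later given either 17β-estradiol (E2) under the skin at 115 µg/kg or olive oil vehicle, and RNA was taken 18 h after that. The labels call RNA of the vertebral bodies L5 and L6 trabecular bone and RNA of flushed long-bone shafts cortical bone. For the shafts, the protocol names femora and tibiae while the sample characteristics name the femur alone, and this difference was left open. Bone, genotype and treatment make 8 groups of 5 arrays, and grouping was taken from the labels alone. The labels number the replicates, and each number stands for 1 BeadChip that carries 1 array of every group. They do not say whether both bones came from the same mice or whether the replicates are separate animals, so the p-values measure the spread between these samples, which may be partly technical.

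Per the file headers and the labels, the deposited table holds the mean bead intensity of each probe from GenomeStudio, whose version is not given in the sources used here. The deposited intensities were not background-subtracted and not normalized between arrays, as judged from their values. Per the file headers, each intensity has a detection p-value, the share of negative control beads at least as bright. A second deposited table by the authors holds intensity on a linear scale after quantile normalization over all 40 arrays, again judged from the values, since its method is not given in the sources used here. Each of its columns had a rank correlation of 1 with the array it was matched to, and 0 columns were without a sample. The table held 25697 probes with 18138 different symbols, which became 17914 genes after symbols were brought up to date. Of the probes, 20733 were named by a current symbol, 3 by a symbol in another letter case and 3903 by a synonym, and 1058 kept the name in the file.

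The intensities were background-corrected with the detection p-values, offset by 16, quantile-normalized over the 40 arrays and put on the log2 scale with limma's neqc (R 4.3.3, limma 3.58.1, statmod 1.5.0). A probe was kept if its detection p was under 0.01 on at least 5 arrays of the fit, and each gene was represented by its brightest kept probe. Array signal over background sets how small a difference can be seen, and the number of arrays limits the precision. Group means were fitted with limma (lmFit and eBayes) and p-values were adjusted by Benjamini and Hochberg over all genes tested in a comparison. A gene was called at an adjusted p under 0.05. Comparisons within a bone used its 20 arrays, and comparisons between the bones used all 40. The 10 comparisons were the E2 effect in each bone and genotype, its difference between genotypes in each bone, the genotype difference in vehicle-treated bone, the difference between the bones of vehicle-treated wild type, and the difference in E2 effect between the bones of wild type. Errors given with log2 differences are standard errors of the limma fit, and errors given with group means are standard deviations over 5 arrays. Where a gene was detected on 0 arrays of the lower group, its fold is a lower bound, taken on background-corrected values against the level at which the probe would have been detected.

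Gene lists were tested with fry, a limma test of whether the genes of a list move on balance one way, which does not compare them with other genes. There were 30 lists with 756 genes, of which 704 were on the array, and a list needed at least 5 measured genes. List p-values were adjusted over the lists of a comparison. An E2 response score was the mean log2 value of the genes called higher with E2 in wild type of the other bone minus that of the genes called lower there, as far as they were measured in the bone scored. Its E2 minus vehicle differences within each BeadChip were compared between genotypes by an exact permutation test over all splits of the 10 values, two-sided. For a check of the pairing by BeadChip, residuals of same-numbered arrays were correlated across genes, which are not independent replicates. The mean correlation ran from 0.0386 to 0.320 in trabecular bone and from −0.0478 to 0.367 in cortical bone, and the lowest pair had −0.588. The fits had no term for the BeadChip, which was run as an alternative, the replicate block.

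The named genes of a comparison were those with an adjusted p under 0.05 and the same sign on all 5 BeadChips, up to 10 with the largest positive and 10 with the largest negative log2 difference, without clone and locus names. Up to 4 called members of each list were added, and so were Esr1, Esr2, Pgr, Greb1, Runx2, the Bglap genes, Sost, Tnfsf11 and Tnfrsf11b in every comparison. Where fewer than 5 genes passed, the 5 with the smallest p were named. Members named from an adjustment over a list alone, and called genes outside this rule, were chosen after their values were seen. The groups, comparisons, tests, thresholds, gene lists and naming rule were set before the data were examined, and so were the alternatives unless stated otherwise.

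The alternatives were no background correction, an offset of 50, quantile normalization within a bone, the authors' values, median scaling, no filter or a stricter filter on dim probes, all probes tested, other sets of arrays in the fit, the replicate block as a fixed or random term, a trend with robust empirical Bayes, array quality weights, an adjusted p under 0.01, and leaving out each array and each BeadChip. Lists were also tested with camera, with an estimated correlation between genes and with a preset one of 0.01. Alternatives chosen after seeing the data were leaving out BeadChip 1 with the replicate block, the mean of skeletal muscle markers as a covariate, and median scaling for the lists.

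The fits were tested on simulated data built from the residuals of these arrays, with 3 simulations per comparison. A log2 change of 1 was recovered for 64% of changed genes in the wild-type trabecular comparison and for 60% in the wild-type cortical one, and a change of 2 for 98% and 96%. For the difference between genotypes, a change of 1 was recovered for 30.7% in trabecular and 20% in cortical bone, and a change of 2 for 78% and 84%. False calls made up 0.732% to 5.39% of calls over the 6 comparisons simulated. For each size of change, 150 genes were changed over the 3 simulations, and a comparison had 307 to 428 calls. So many changed genes ease the adjusted threshold. Where few genes are called, as in the real E2 comparisons, the shares recovered above are too high. The score test had p under 0.05 in 2.5% of 40 simulations with equal effects and in 100% with a share of 0.3. These simulations raised 12 random genes and had no lower gene. They do not cover the choice of score genes on wild-type arrays or the weight of a single lower gene. No sample was left out, and no sequence or genome file was used here. The position of the Esr1 probes relative to the deleted part of the receptor is not known here, so they do not check the genotype.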

Results

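The data hold gene expression in vertebral trabecular bone and long-bone cortical bone of ovariectomized mice, 18 h after E2 or vehicle, in wild type and in mice without ERα AF-1. Each of the 8 groups had 5 arrays. In trabecular bone, 8052 to 9218 probes were detected on the 4 arrays of BeadChip 1 and 10357 to 11203 on the 16 arrays of BeadChips 2 to 5. In cortical bone, the 4 arrays of BeadChip 1 had 9880 to 11435 detected probes and the other 16 had 10324 to 11691. Of the genes read in every comparison, osteocalcin (Bglap1, Bglap2, Bglap3) and osteoprotegerin (Tnfrsf11b) were detected on all 20 arrays of each bone. Esr1, the gene of ERα, was detected on 17 trabecular and 20 cortical arrays and RANKL (Tnfsf11) on 10 and 19. The osteocyte Wnt inhibitor sclerostin (Sost) was detected on 0 trabecular and 19 cortical arrays. Esr2, Pgr and Runx2 were detected on 0 arrays in either bone and Greb1 on 0 trabecular and 3 cortical arrays, so these 4 genes were not tested.

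**Figure D1:**
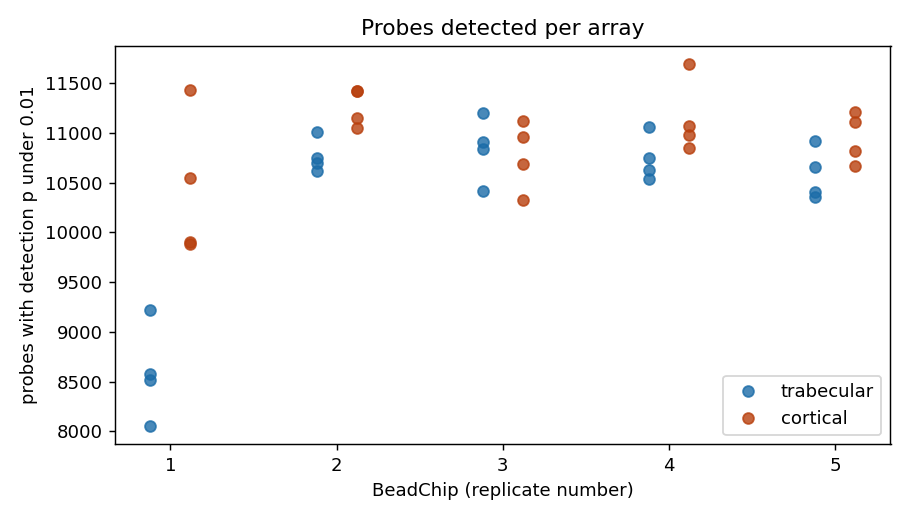
Number of probes with a detection p under 0.01 on each of the 40 arrays (vertical axis), by BeadChip (horizontal axis) and bone (colour). The 4 trabecular arrays of BeadChip 1 lie between 8052 and 9218, below all other arrays.

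The first question was what E2 does in trabecular bone of wild-type mice, which had lost ovarian estrogen. E2 raised Myl10, a myosin regulatory light chain, which was detected on 5 of 5 E2 arrays and 1 vehicle array. Its size depends on the handling of background: the fit gave a log2 difference of 2.43 ± 0.22, and 1.25 without background correction. Tmem86a, a lysoplasmalogenase, rose from 9.94 ± 0.28 to 11.52 ± 0.29 on the log2 scale (SD, n = 5). The limb homeobox gene Shox2, undetected on all vehicle arrays, was at least 1.96-fold higher. That bound rests on background-corrected values, and over the alternatives the fitted log2 difference of Shox2 ranged from 0.77 to 2.17. Vldlr, the VLDL receptor, rose from 9.72 ± 0.34 to 11.22 ± 0.13 (SD, n = 5). Further genes that rose encode the signalling adaptor Grb7 (1.42 ± 0.20), the potassium channels Kcnk2 (1.63 ± 0.25) and Kcnk1 (1.29 ± 0.23), the matrix cross-linking enzyme Loxl1 (0.98 ± 0.16) and the growth hormone receptor (Ghr, 0.83 ± 0.15). Fam78b (1.77 ± 0.28), the neuropeptide precursor Cartpt (3.19 ± 0.64) and the forkhead factor Foxc1 (1.35 ± 0.28) also rose. Over the alternatives the log2 difference ranged from 0.69 to 1.95 for Fam78b, 1.62 to 3.76 for Cartpt and 0.70 to 1.52 for Foxc1. For Kcnk2 it ranged from 0.72 to 1.80, for Kcnk1 from 0.81 to 1.46 and for Grb7 from 0.86 to 1.64. The clock repressor Per2 fell by 0.90 ± 0.18.

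With limma, 18 of 8693 genes were called, 17 higher and 1 lower, each in the same direction on 5 of 5 BeadChips. An unadjusted p under 0.05 was found for 589. Without any effect, a share of about 0.05 of the genes tested would have such a p. The count lay above that share here and between the bones of vehicle-treated wild type. In every other comparison it lay below, so those counts show no excess. Adjusted p was 5.91e-06 for Myl10, 3.02e-05 for Tmem86a and Shox2, 0.000609 for Vldlr, 0.00159 for Grb7, 0.00235 for Kcnk2, 0.00362 for Fam78b, 0.00486 for Loxl1, 0.0138 for Kcnk1 and 0.0172 for Ghr. It was 0.0363 for Per2, 0.042 for Cartpt and 0.0483 for Foxc1, and with the replicate block these became 0.0581, 0.0805 and 0.0832. Over the alternatives the call was lost for Per2 in 19 of 32, Cartpt in 16 of 31 and Foxc1 in 18 of 31. It was also lost for Ghr in 12 of 32 and Kcnk1 in 10 of 31. The other called genes were Rasl11a, Gdpd2, Tex2, Bicc1 and Insc. With the replicate block Bicc1 lost its call as well (0.0581), Wnt4 was called (0.0249), and 16 genes passed, 14 of them among the 18. Tnfsf11 had 0.73 (adjusted p = 0.705), Tnfrsf11b −0.13, Esr1 −0.68 ± 0.31 (adjusted p = 0.731), Bglap1 0.48 (adjusted p = 0.684), Bglap3 0.44 and Bglap2 0.00, and none passed the threshold. The count was 4 after median scaling, 10 at an adjusted p under 0.01 and 47 with array quality weights. It was 30 without BeadChip 1, 42 without it and with the replicate block, and as low as 8 without BeadChip 3 or BeadChip 4.

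**Figure D2:**
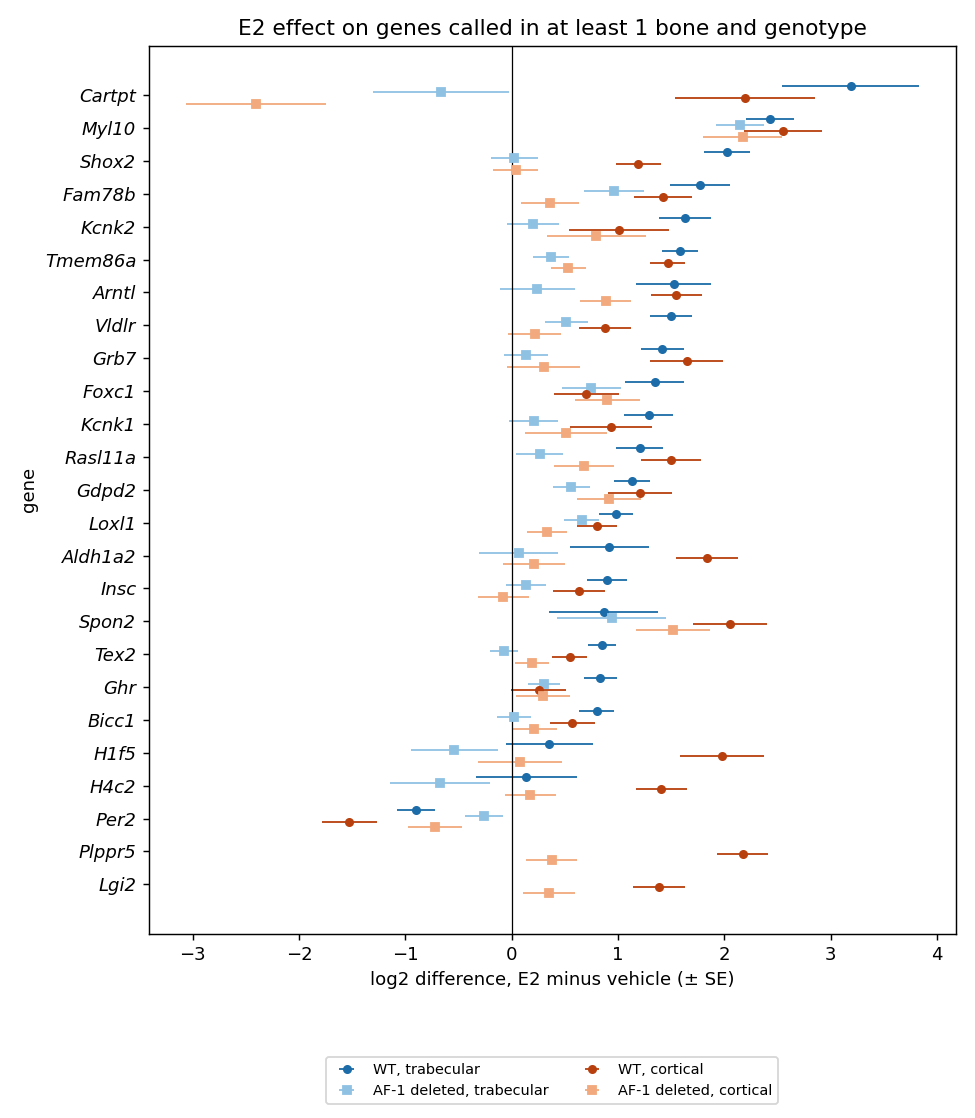
Log2 difference, E2 minus vehicle, with its standard error (horizontal axis), for the genes called in at least 1 bone and genotype (vertical axis). Symbols mark wild type and AF-1 deletion in each bone, 5 arrays per group. Values of genes undetected in a group, such as Shox2 in trabecular bone other than wild type with E2, are limited by background and give no size; Tmem86a lies at 1.58 and 1.47 in wild type and 0.37 and 0.53 with the deletion.

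Matrix genes rose together with E2 in wild-type trabecular bone. Of 26 measured collagens and matrix genes, 25 had a positive difference, with a median of 0.44 (fry adjusted p = 0.0043). Among them 1 was called over all genes tested, Loxl1, and 8 adjusted over the list alone, including Thbs1 (1.54 ± 0.37), Lox (1.11 ± 0.24), Col6a2 (0.95 ± 0.22) and Plod2 (0.73 ± 0.22). Wnt pathway genes rose as a list (median 0.34, 11 of 14 positive, fry adjusted p = 0.0043), with 0 called over all genes and 2 adjusted over the list alone, Wnt4 (1.14 ± 0.24) and Ccn5 (0.65 ± 0.21). Megakaryocyte and platelet markers rose (median 0.19, 12 of 13 positive, fry adjusted p = 0.0249), with 0 called over all genes and 4 adjusted over the list alone: Pf4 (0.73 ± 0.27), Clec1b (0.57 ± 0.21), Ppbp (0.44 ± 0.14) and Thbs1, which is also among the matrix genes. These 3 lists kept their call with an estimated correlation.

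The other 4 lists called did not. Marrow stromal markers moved up (median 0.03, 10 of 16 positive, fry adjusted p = 0.0271; adjusted p = 0.146 with an estimated correlation), with Foxc1 the 1 member called, over all genes and adjusted over the list alone. Apoptosis and p53 response genes moved up (median 0.14, 19 of 22 positive, fry adjusted p = 0.0383; adjusted p = 0.0964 with an estimated correlation), with 0 members called over all genes or adjusted over the list alone. Runx2 target genes moved up (median 0.16, 14 of 20 positive, fry adjusted p = 0.0474; adjusted p = 0.0964 with an estimated correlation), with 0 called over all genes. Adjusted over the list alone, 3 were higher, the mineralization genes Phex (0.73), Ibsp (0.67) and Alpl (0.52), and 1 was lower, Cst7 (−0.70). Circadian clock genes moved down (median −0.69, 7 of 10 negative, fry adjusted p = 0.0383; adjusted p = 0.0964 with an estimated correlation), with Per2 called over all genes. Adjusted over the list alone, Dbp (−1.45), Per1 (−1.05), Per2 and Tef (−0.82) were lower and the clock activator Arntl (1.52) was higher.

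Skeletal muscle markers, which are not bone genes, had a mean difference of 0.56 ± 0.75 (SD over 5 BeadChips) in the same arrays, with 26 of 27 positive, and did not pass the test (fry adjusted p = 0.195). Osteoblast markers (fry adjusted p = 0.0953), estrogen-responsive genes (0.527), osteocyte markers (0.11) and osteoclast markers (0.086) did not pass either; with the replicate block the last 2 reached 0.0335 and 0.0474. Without background correction all 7 lists stayed called by fry, with smaller medians, such as −0.27 for circadian, 0.20 for Wnt and 0.31 for matrix genes. After median scaling 0 of the 7 lists stayed called (fry adjusted p = 0.981 for each). The median then was 0.35 for matrix, 0.31 for Wnt, 0.17 for megakaryocyte, 0.13 for Runx2 target, 0.08 for apoptosis and −0.53 for circadian genes, and that of the marrow stromal markers turned to −0.03. Without BeadChip 1 and with the replicate block, the matrix, Wnt, megakaryocyte and Runx2 target lists kept their call, while adjusted p was 0.07 for the marrow stromal, 0.134 for the apoptosis and 0.154 for the circadian list. For the RANKL-OPG, IGF axis, cell cycle and neutrophil lists, none called, the median, mean and test differed in sign.

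The same question was asked of wild-type cortical bone. E2 raised Tmem86a from 10.31 ± 0.16 to 11.78 ± 0.32 (SD, n = 5) and Myl10 by 2.55 ± 0.37, or 1.40 without background correction. Plppr5, a membrane protein related to phospholipid phosphatases, was undetected on all vehicle arrays and at least 2.63-fold higher with E2. This bound also rests on background-corrected values, and the fitted log2 difference of Plppr5 ranged from 0.85 to 2.37 over the alternatives. The clock pair moved in opposite directions, with Arntl up by 1.55 ± 0.24 and Per2 lower (−1.52 ± 0.26). Aldh1a2, an enzyme of retinoic acid synthesis (1.84 ± 0.29), the secreted matrix protein Spon2 (2.05 ± 0.35), Fam78b (1.42 ± 0.28), Shox2 (1.19 ± 0.21), Lgi2 (1.38 ± 0.25) and the histones H1f5 (1.98 ± 0.40) and H4c2 (at least 1.37-fold) rose as well. Rasl11a, a Ras-like GTPase, rose 2.83-fold from 6.80 ± 0.54 with vehicle (SD, n = 5). Over the alternatives its log2 difference ranged from 0.72 to 1.74, and that of Aldh1a2 from 0.78 to 2.10.

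With limma, 13 of 9096 genes were called, 12 higher and 1 lower, each in the same direction on 5 of 5 BeadChips, and 285 had an unadjusted p under 0.05. Adjusted p was 8.63e-05 for Tmem86a and Plppr5, 0.00294 for Myl10, 0.00512 for Arntl, 0.00762 for Aldh1a2, 0.0116 for Per2, Spon2 and H4c2, 0.0157 for Shox2 and Lgi2, 0.0263 for Rasl11a, 0.0353 for Fam78b and 0.0499 for H1f5. Over the alternatives the call was lost for H1f5 in 23 of 31, Rasl11a in 16 of 31 and Fam78b in 14 of 31. It was also lost for H4c2 in 9 of 31 and for Per2 and Spon2 in 7 of 32 each. Sost had 1.39 ± 0.37 and was not called over all genes (adjusted p = 0.338), but passed adjusted over the list alone of osteocyte markers (0.0152). Bglap1 (0.01), Bglap2 (0.05), Bglap3 (0.14), Tnfrsf11b (0.41), Tnfsf11 (0.03) and Esr1 (−0.15) were not called. By limma's fry, 0 of 30 lists were called. The circadian list, with 9 of 13 genes negative, had the smallest p in limma's fry (0.0913, adjusted p = 0.866). Members that passed adjusted over the list alone included Stc2 (2.01), Wnt4 (1.34), Thbs1 (1.23), Loxl1 (0.80), Dbp (−1.71) and Per3 (−1.13). The skeletal muscle markers varied within these groups, at 12.3 ± 1.16 with E2 and 12.4 ± 0.76 with vehicle (SD, n = 5). The count was 5 with probes detected on all arrays, 30 with all 40 arrays in the fit, 6 with the arrays of these groups alone, 5 at an adjusted p under 0.01, and 7 without BeadChip 1 and with the replicate block. The replicate block alone gave 19, calling Stc2, Dbp, Wnt4, Grb7, Per3 and Whrn in addition. It was 3 without BeadChip 3, 4 without BeadChip 4, 8 without BeadChip 1 or BeadChip 2, and 5 and 8 without the E2 arrays of replicates 3 and 4.

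The E2 responses of the bones overlapped. Of the 18 genes called in wild-type trabecular bone, 18 had the same direction in cortical bone, 17 of them with an unadjusted p under 0.05. Called in both were Myl10, Tmem86a, Shox2, Fam78b and Rasl11a, all higher, and Per2, lower. Among 8506 genes tested in both, independent lists would share 0.02 higher and 0.000118 lower genes. The bones share BeadChips and may share mice, so these lists may not be independent. The E2 effect differed between the bones for 1 of 9451 genes, Plppr5 (adjusted p = 0.0191, lower on 5 of 5 BeadChips), and 256 genes had an unadjusted p under 0.05. Plppr5 was detected on 5 of 5 cortical E2 arrays and on 0 of the cortical vehicle and the trabecular arrays of wild type, so the difference has no size: the fit gave −1.75 ± 0.31 for trabecular minus cortical, and −0.68 without background correction. That call ended without background correction (0.472), with the authors' values (0.428), after median scaling (0.112), with trend and robust empirical Bayes (0.106), with array weights (0.0761), with the arrays of these groups alone (1), and without BeadChip 1 and with the replicate block (0.644), as it did without any of BeadChips 1, 3, 4 and 5 or any of 8 single arrays. Stc2 (−2.03 ± 0.57), Ildr1 (−1.29 ± 0.34), Tepsin (−1.49 ± 0.44), Gsk3a (−1.08 ± 0.29) and Sost, detected on 0 trabecular arrays, did not pass (adjusted p = 1), and 0 of 30 lists were called by fry.

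The next question was what E2 does without AF-1. In trabecular bone with the deletion, Myl10 was undetected on all vehicle arrays and at least 1.95-fold higher with E2. The bound rests on background-corrected values, and the fitted log2 difference ranged from 0.81 to 2.22 over the alternatives. Myl10 was the 1 gene called of 8693 (adjusted p = 4.9e-05, higher on 5 of 5 BeadChips), and 362 genes had an unadjusted p under 0.05 with limma. With a filter that kept probes detected on all arrays, Myl10 was not tested and the count was 0. The next genes by p were Tenm4 (0.90 ± 0.21), Loxl1 (0.66 ± 0.16), the heat shock protein Hsph1 (0.70 ± 0.18) and the fatty acid desaturase Scd1 (1.01 ± 0.26), which did not pass (adjusted p = 0.964). Esr1 (−0.59), Tnfsf11 (−0.17) and Bglap1 (0.07) did not pass either. Adjusted over the list alone, and not over the 30 lists, Loxl1, Hsph1, Scd1, Wnt4 (0.85), Lpl (0.59) and Creld2 (0.59) passed. By limma's fry, 0 of 30 lists were called, and the smallest p was that of the IGF axis (0.00683, adjusted p = 0.205).

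In cortical bone with the deletion, 0 of 9096 genes were called with limma. An unadjusted p under 0.05 was found for 318, which is below a share of 0.05 of the genes tested. Myl10 had 2.17 ± 0.37 (adjusted p = 0.0822), or 0.95 without background correction (0.682), Spon2 1.52 ± 0.35 (0.703), the immediate early gene Fos 1.11 ± 0.26 (0.73) and Sost 0.54. The secreted Wnt modulator Sfrp4 (adjusted p = 0.18) and Rnmt, an mRNA cap methyltransferase (0.481), were undetected on all vehicle arrays and did not pass. Adjusted over the list alone, Fos, Sfrp4, Arntl (0.88), Hspa5 (0.82), Wif1 (−0.73), Dbp (−1.55), Tef (−0.86) and Per2 (−0.72) passed. That adjustment was not made over the 30 lists, and 0 of 30 lists were called by fry. The count was 48 with array quality weights, 1 after median scaling, 1 with all 40 arrays, 1 with the arrays of these groups alone, 2 without the vehicle array of replicate 5 and 1 without BeadChip 5.

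Whether the E2 response depends on AF-1 was tested as the difference between genotypes. All 18 genes called in wild-type trabecular bone had a smaller difference with the deletion, their median falling from 1.32 to 0.26, and 16 kept the direction. All 13 called in cortical bone kept the direction with a smaller difference, their median falling from 1.52 to 0.38. Those genes were chosen on the wild-type arrays, which by itself favours larger values there, and Shox2 in trabecular bone and Plppr5 and Aldh1a2 in cortical bone were undetected with the deletion. The E2 response score used genes called in the other bone. Whether both bones came from the same mice is not stated; if they did, this choice still favours wild type and the tests of the bones are not independent. In trabecular bone the score was higher with E2 by 2.18 ± 0.71 in wild type and 0.64 ± 0.36 with the deletion (SD, n = 5 BeadChips, positive on 5 of 5 in each), 29.2% of the wild-type difference. In cortical bone it was higher by 2.67 ± 0.30 and 1.07 ± 0.61 (SD, n = 5, positive on 5 of 5 in each), or 40.1%. The differences between genotypes were 1.54 and 1.60. Each had an exact permutation p of 0.00794, two-sided, the smallest that 5 values against 5 can give, and 0.00794 adjusted over the bones. The only lower gene in each score was Per2, so Per2 weighs as much as the 10 or 17 higher genes together. Its E2 effect, deleted minus wild type, differed by 0.64 in trabecular and 0.80 in cortical bone, which enters these score differences in full. With the first 50 genes by p of the other bone, of which 38 higher and 8 lower ones were measured in trabecular bone, the differences were 0.70 and 0.73, and the deletion had 42.2% and 48.1% of the wild-type value. With the authors' values or without background correction the trabecular score with the deletion was positive on 4 of 5 BeadChips.

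**Figure D3:**
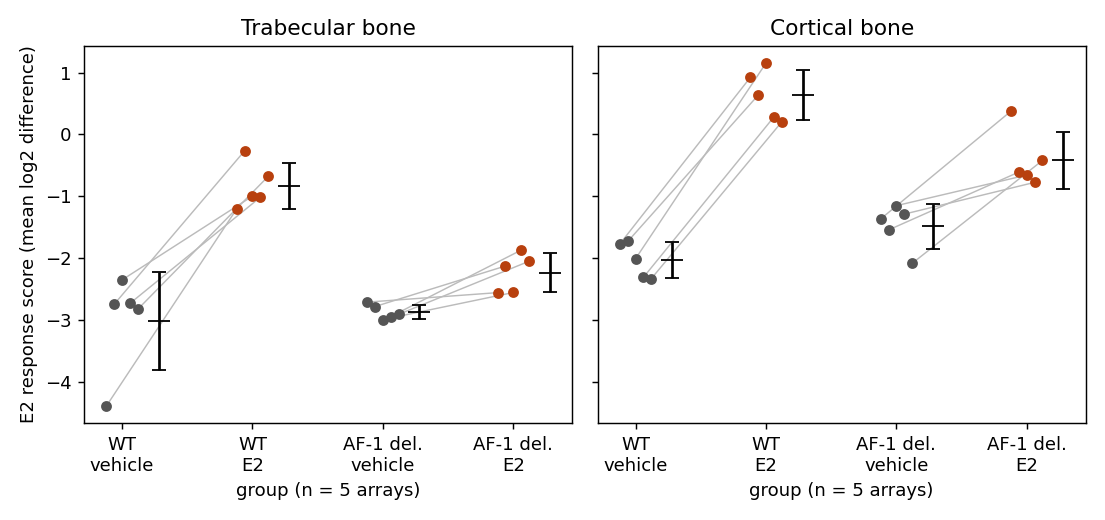
E2 response score of each array (vertical axis, mean log2 difference) by group (horizontal axis), with mean and standard deviation of 5 arrays; grey lines join arrays of the same BeadChip. In trabecular bone the wild-type mean goes from −3.01 with vehicle to −0.83 with E2 and the AF-1-deleted mean from −2.87 to −2.23; in cortical bone from −2.03 to 0.64 and from −1.49 to −0.42.

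Gene by gene, the difference passed for Shox2 in trabecular bone (adjusted p = 0.0219, lower on 5 of 5 BeadChips). Shox2 was detected on 5 of 5 wild-type E2 arrays and on 0 arrays of the other 3 groups, so the difference has no size: the fit gave −2.00 ± 0.31, and −0.76 without background correction. It was the 1 gene called of 8693 with limma, and 322 had an unadjusted p under 0.05. With the replicate block its adjusted p was 0.0745 and Kcnk2 was called in its place. The Shox2 call also ended without background correction (0.0835), with the authors' values (0.0808), with trend and robust empirical Bayes (0.169), after median scaling (0.726), without any of BeadChips 2 to 5, and without any of 9 single arrays. Tmem86a (−1.21 ± 0.24, adjusted p = 0.25), Tex2 (−0.92 ± 0.19, 0.256), Fam118b (1.04 ± 0.23, 0.338), Grb7 (−1.28 ± 0.29, 0.421) and Kcnk2 (−1.43 ± 0.35, 0.609) did not pass over all genes. Kcnk2 passed adjusted over the list alone of osteocyte markers (0.00449), as did the platelet gene Gp9 (−0.91, 0.0294) over its own list.

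In cortical bone 0 of 9096 genes differed in E2 effect between genotypes with limma, and 212 had an unadjusted p under 0.05. Values with the smallest p were those of Plppr5 (adjusted p = 0.35), detected on the wild-type E2 arrays alone, and Cartpt (−4.60 ± 0.93, 0.368). They were followed by Tmem86a (−0.93 ± 0.23), Aldh1a2, which was undetected with the deletion, and Shox2 (−1.15 ± 0.30), each with adjusted p = 1. Sost had −0.85 ± 0.52. By fry, 0 of 30 lists were called in either bone. In cortical bone the count was 1 with all 40 arrays, 1 with array quality weights, and 1 without the AF-1-deleted vehicle array of replicate 5 or without BeadChip 5.

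Without E2, the genotypes were compared to see what the deletion does alone. In trabecular bone 0 of 8693 genes were called with limma and 371 had an unadjusted p under 0.05. The formyl peptide receptor Fpr1 had 1.09 ± 0.20 (deleted minus wild type, adjusted p = 0.169), Ogfrl1 0.83 ± 0.16 (0.267), Agap3 −1.06 ± 0.24 (0.772) and Esr1 −0.08 ± 0.31. Msantd1 and Myl10 (adjusted p = 0.942 for each) were undetected with the deletion and did not pass. In cortical bone 0 of 9096 genes were called and 256 had an unadjusted p under 0.05. Cartpt had 2.93 ± 0.66, Ranbp3l 0.97 ± 0.24, Acox3, a peroxisomal oxidase, 0.64 ± 0.16, Arid4b −0.71 ± 0.20, Cbln1 1.12 ± 0.32 and Esr1 0.14 ± 0.25 (each adjusted p = 1). By fry, 0 of 30 lists were called in either bone; without BeadChip 1 and with the replicate block, erythroid markers were called lower in trabecular bone with the deletion (adjusted p = 0.0383).

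The bones themselves were compared in vehicle-treated wild type, as trabecular minus cortical. The trabecular samples were vertebral bodies and the cortical ones flushed long-bone shafts. Bone type, skeletal site and the share of other tissues therefore cannot be told apart as sources of a difference. Genes of muscle, cartilage and matrix were among those that differed most. The striated muscle genes Myl3 (−6.33 ± 0.47), Tnnc1 (−4.80 ± 0.60) and Myl2 (−4.53 ± 0.54), the growth factor gene Ptn (−4.31 ± 0.51) and Abra (−4.09 ± 0.59), Prss35 (−3.91 ± 0.38), Lrrc15 (−3.90 ± 0.49), Yipf7 (−3.82 ± 0.54) and Ppp1r27 (−3.79 ± 0.61) were lower in trabecular bone. Col3a1, a fibrillar collagen, was at least 11.9-fold lower. Higher in trabecular bone were the alpha-1-antitrypsin genes Serpina1b (at least 11.3-fold) and Serpina1d (at least 10.8-fold), and the cartilage genes Cytl1 (at least 10.5-fold), Mia (at least 6.92-fold), Col9a2 (3.37 ± 0.46), Acan (3.03 ± 0.52), Chad (2.06 ± 0.57) and Hapln1 (at least 1.54-fold). Melanotransferrin (Meltf, at least 2.56-fold) and the histone H4c14 (1.93 ± 0.32) were higher too. The bounds rest on background-corrected values: without that correction the fitted difference was 2.37 for Serpina1b and Serpina1d, 2.23 for Cytl1, 1.69 for Mia and −2.37 for Col3a1. With limma, 1950 of 9451 genes were called, 852 higher and 1098 lower, 784 of them by more than 1 on the log2 scale, and 1754 had the same sign on 5 of 5 BeadChips. The median over all genes was 0.06, and 3210 genes had an unadjusted p under 0.05.

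Osteocyte and osteoblast genes were lower in trabecular bone. Of 12 osteocyte markers, 10 were called lower and 1 higher over all genes, and 10 lower and 2 higher adjusted over the list alone (median −1.73, fry adjusted p = 4.14e-12): Mepe (−3.24 ± 0.30), Ackr3 (−2.88), Irx5 (−2.02) and Sost, at least 1.77-fold lower (adjusted p = 8.38e-08). Of 16 osteoblast markers, 11 were called lower and 12 adjusted over the list alone (median −0.87, fry adjusted p = 3.6e-08), with Fmod (−2.37), Omd (−2.08), Alpl (−1.65) and Dlx3 (−1.54). Of 27 collagens and matrix genes, 24 were called lower and 25 adjusted over the list alone (median −1.15, fry adjusted p = 1.56e-08), with Thbs2 (−3.05), Col12a1 (−2.34) and Col5a2 (−2.10). Of 25 Runx2 target genes, 12 were called lower, and 15 lower and 2 higher adjusted over the list alone (fry adjusted p = 4.41e-09), including Phex (−1.72) and the osteoblast factor Sp7 (−1.33). Wnt pathway genes (12 of 23 called lower, 17 adjusted over the list alone, fry adjusted p = 1.54e-09) included Wnt16 (−2.46), Dkk3 (−2.39) and Ccn4 (−2.07). The TGF-beta and BMP list had 12 of 25 called lower, and 15 lower and 1 higher adjusted over the list alone (fry adjusted p = 1.4e-08). Bglap3 was lower, at 13.77 ± 0.38 against 14.77 ± 0.14 (SD, n = 5, limma adjusted p = 2.23e-05). Bglap1 (−0.55 ± 0.15, 0.00933) and Tnfrsf11b (−1.71 ± 0.35, 0.00046) were lower. Bglap1 lost its call in 4 of 29 alternatives, with adjusted p up to 0.741 after median scaling, and ranged from −0.38 to −2.24, the latter from another of its probes. Bglap2 (−0.08), Tnfsf11 (−0.61, 0.185) and Esr1 (−0.47, 0.25) did not pass; without BeadChip 1 and with the replicate block Esr1 was called (0.0379).

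Markers of other tissues differed as well. All 29 skeletal muscle markers were called lower in trabecular bone, over all genes and adjusted over the list alone (median −2.63, mean −2.52 ± 1.03 SD over 5 BeadChips, fry adjusted p = 9.22e-07), with Des (−3.11) and Myot (−3.03). Marrow stromal markers (5 of 18 called lower, 6 adjusted over the list alone, fry adjusted p = 2.48e-08), adipocyte markers (8 of 14 called lower, 8 adjusted over the list alone, fry adjusted p = 1.69e-05) and IGF axis genes (7 of 14 called lower, 7 adjusted over the list alone, fry adjusted p = 2.33e-05) were lower too. These lists and the 6 before them kept their call with an estimated correlation. Endothelial markers (11 of 18 called lower, 13 lower and 1 higher adjusted over the list alone, fry adjusted p = 2.33e-05) lost it, at adjusted p = 0.0652 with an estimated correlation. So did circadian genes (4 of 13 called lower, 7 adjusted over the list alone, fry adjusted p = 0.000297), among them Dbp (−1.54) and Nr1d1 (−1.15), at adjusted p = 0.0961 with an estimated correlation. Estrogen-responsive genes (3 of 20 called lower, 3 adjusted over the list alone, fry adjusted p = 0.00407) had adjusted p = 0.197 with an estimated correlation and glucocorticoid-responsive genes (5 of 18 called lower, 6 adjusted over the list alone, fry adjusted p = 0.00625) had adjusted p = 0.224 with an estimated correlation. Oxidative phosphorylation genes (6 of 49 called lower, 0 adjusted over the list alone, fry adjusted p = 0.0112) had adjusted p = 0.262 with an estimated correlation.

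Erythroid, chondrocyte, T and NK cell, cell cycle, B-lineage and interferon-response lists were higher in trabecular bone, and all 6 lost their call with an estimated correlation. Erythroid markers (15 called higher and 1 lower of 29, 17 and 1 adjusted over the list alone, median 0.66, fry adjusted p = 0.000568) included Epor (1.27) and Gata1 (1.13), with adjusted p = 0.15 with an estimated correlation. Chondrocyte markers (6 called higher and 1 lower of 13, 7 and 1 adjusted over the list alone, median 1.18, fry adjusted p = 0.000205) also had adjusted p = 0.15 with an estimated correlation. Without background correction the median was 0.58 for chondrocyte markers and −1.12 for osteocyte markers. T and NK cell markers (7 of 14 called higher, 9 adjusted over the list alone, fry adjusted p = 0.000205) included Cd2 (1.10) and Cd3d (0.85), with adjusted p = 0.108 with an estimated correlation. Cell cycle genes (9 of 33 called higher, 10 adjusted over the list alone, fry adjusted p = 0.0041), with Foxm1 (1.05) and Aurka (0.72), and B-lineage markers (6 of 20 called higher, 10 adjusted over the list alone, fry adjusted p = 0.00559), with Blk (1.08) and Cd37 (0.94), had adjusted p = 0.224 with an estimated correlation. Interferon-response genes (6 of 29 called higher and adjusted over the list alone, fry adjusted p = 0.0241), with Oas3 (1.76) and Dhx58 (1.11), had adjusted p = 0.357 with an estimated correlation. Osteoclast (fry adjusted p = 0.345), neutrophil (0.15) and immediate early genes (0.0534) did not pass; without BeadChip 1 and with the replicate block neutrophil markers were called higher (0.0472) and immediate early genes lower (0.00177). For the osteoclast and the apoptosis and p53 lists, not called, the median, mean and test differed in sign.

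**Figure D4:**
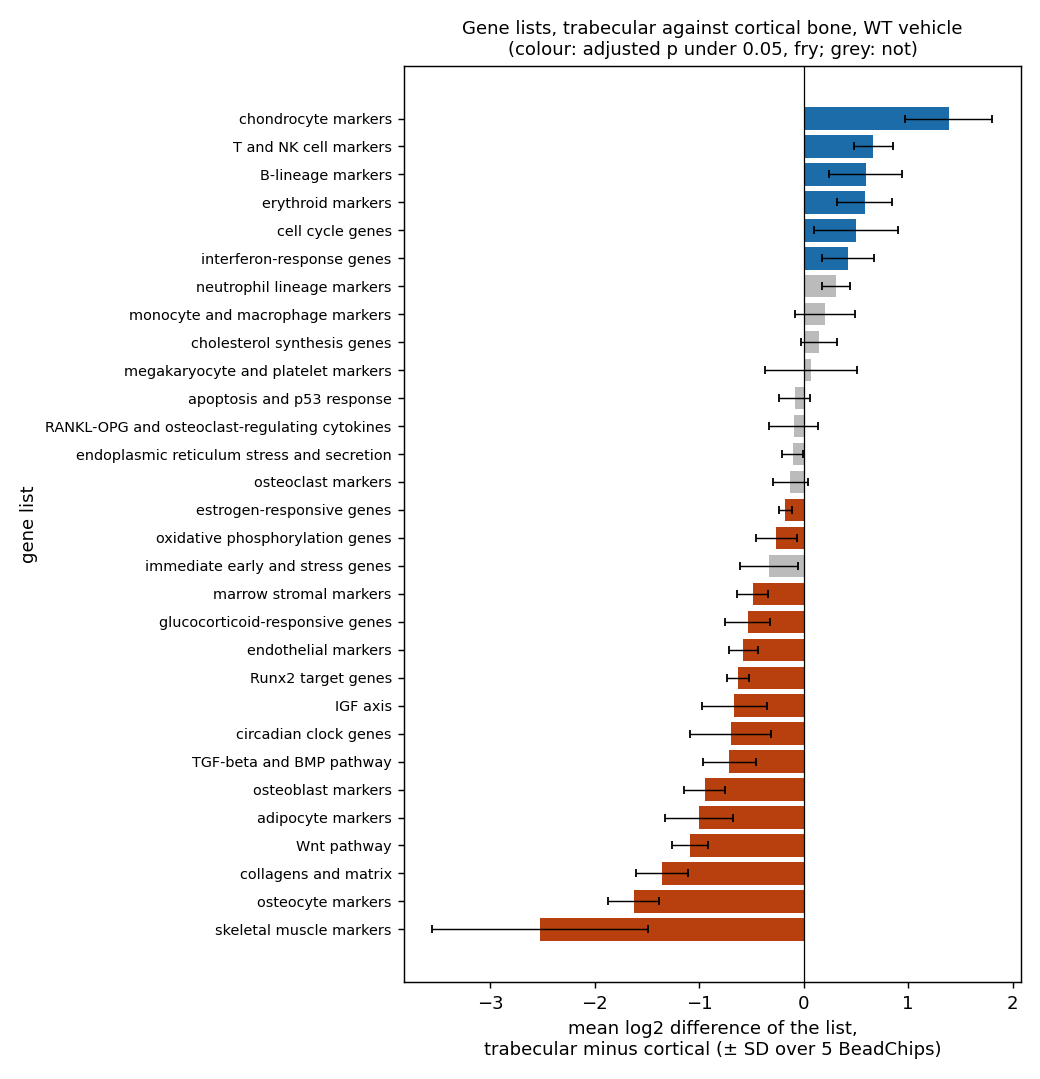
Mean log2 difference of each of 30 gene lists, trabecular minus cortical bone of vehicle-treated wild type (horizontal axis), with the standard deviation over 5 BeadChips; colour marks lists with a fry adjusted p under 0.05. Skeletal muscle markers have the lowest mean, −2.52, and 21 lists are called, 15 lower and 6 higher.

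The count of genes differing between the bones was 718 after median scaling (91 higher and 627 lower), 1019 at an adjusted p under 0.01 (332 higher and 687 lower) and 3256 without BeadChip 1 and with the replicate block. There 1751 were higher and 1505 lower, so which direction held more genes depended on the setting. It was 866 without BeadChip 4, 1295 without BeadChip 2, 1297 without BeadChip 5, and 1262 without the cortical vehicle array of replicate 4. After median scaling 9 of the 21 lists stayed called: osteocyte, Wnt, skeletal muscle, matrix, chondrocyte, TGF-beta, adipocyte, circadian and Runx2 target genes.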

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

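The regroupings of the arrays and the test for compressed differences were set beforehand; the tests without BeadChip 1 and of osteoblast-lineage markers were chosen after the score was seen. The 4 trabecular arrays of BeadChip 1 stood apart from their groups in the number of probes detected. The gap to the nearest array, as a share of the group's range, was 0.923 in wild type with E2 (8512 against a median of 10746 on the others) and 0.764 in wild type with vehicle (8573 against 10574.5). With the AF-1 deletion it was 0.856 with E2 (9218 against 11030) and 0.889 with vehicle (8052 against 10523.5). Chance alone sets a sample apart in about 1 of 20 groups, and here it was 4 of 8. For the E2 response score, 1 of 8 groups had such an array, wild-type trabecular vehicle replicate 1 (0.766, a score of −4.39 against −2.74). Among the named genes 3 of 94 groups had one: Cartpt on trabecular wild-type E2 replicate 3 (0.761, 8.41 against 9.59), Fam78b on cortical wild-type E2 replicate 5 (0.771, 9.67 against 8.80) and Ptn on cortical wild-type vehicle replicate 3 (0.745, 9.27 against 10.71).

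The effect of E2 differed between groups by a test of the difference itself in 4 results. The fit gave −2.00 for Shox2 (AF-1-deleted minus wild type, trabecular bone) and −1.75 for Plppr5 (trabecular minus cortical, wild type). Each was detected in 1 of its 4 groups, so neither value is a size: without background correction they were −0.76 and −0.68. The E2 response score differed between genotypes by 1.54 in trabecular and 1.60 in cortical bone.

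The smaller score with the AF-1 deletion was weighed against the dim BeadChip, compressed signal and the content of osteoblast-lineage cells. Without BeadChip 1, with the score genes still chosen on all BeadChips, the lower of the differences was 1.17. The exact permutation p was 0.0286 in both bones, the smallest that 4 against 4 can give, which argues against that BeadChip as the whole cause. Differences between the bones were on average not smaller on the AF-1-deleted E2 arrays: their mean ratio to wild type was 1.12 with a standard error of 0.222 (0.422 to 1.62 over 5 BeadChips). The genes used include all skeletal muscle markers measured. On cortical E2 arrays these had 12.3 ± 1.16 in wild type and 12.8 ± 0.58 with the deletion (SD, n = 5). The ratio may therefore also carry muscle content, and it does not cover dim genes in particular. Markers of the osteoblast lineage in vehicle-treated bone were on average not lower with the deletion. They differed by 0.00189 with a standard error of 0.0721 in cortical and 0.0837 with 0.0473 in trabecular bone. The test set these against the log2 of the score ratio, −1.32 and −1.78. That assumes that a log2 difference with E2 scales with the share of cells, which it need not. The test therefore cannot decide whether cell content plays a part. Whether osteoblast-lineage cells express the score genes was not tested. Other cell types and the time of collection were not weighed for the score. The clock gene Per2 is in the score of both bones and Arntl in that of trabecular bone. Among the explanations left is that the E2 response of the score genes depends in part on AF-1. That hypothesis was found and tested on the same arrays, and perhaps on the same mice.

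Regroupings of the same arrays, 100 per comparison with the real one among them, tested whether chance could give as many genes. For the 18 genes of E2 in wild-type trabecular bone 1 of 100 splits, the real one, gave as many (the highest other 1). The same held for the 1 gene with the deletion (the highest other 0). It also held for the 1950 genes between the bones (the highest other 662, which exchanged the bones of all arrays but 1 of each). For the 13 genes of E2 in wild-type cortical bone 2 of 100 splits gave as many, and the other called 390. That split points to a structure of the samples, since it set arrays with skeletal muscle markers at 10.9 to 11.9 against those at 12.9 to 13.4, and 25 of 29 muscle markers were among its genes. With the muscle markers as a covariate, an alternative chosen after seeing the data, 14 genes were called there (13 of them among the 13), and 13 in wild-type trabecular bone (11 among the 18). For the 1 gene that differed by genotype in trabecular bone 3 of 100 splits gave as many (the highest other 1), and for the 1 that differed between the bones 3 (the highest other 4). For the counts of 0, every split gives as many by construction (100 of 100), so the splits say nothing about chance; the highest other was 0 for E2 with the deletion in cortical bone, 2 for the difference between genotypes there, and 1 and 2 for the genotypes in vehicle-treated trabecular and cortical bone. Most splits do not part all same-numbered pairs, as the real one does, so BeadChip differences enter their contrasts. Splits that do part them are too few for a share under 0.05 in any comparison, so chance was not excluded. Among them 1 of 11, 1 of 14 and 1 of 13 gave as many for wild-type trabecular E2, the deletion and the bones (highest others 0, 0 and 388), and 2 of 11 for wild-type cortical E2 (390). For the genotype and the bone difference in E2 effect it was 1 of 2 and 1 of 3, with the highest other at 0 in both.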

How the results depend on the processing

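The tests that leave out BeadChip 1 with the replicate block, use the muscle covariate, or apply median scaling to the lists were chosen after the results were seen. The E2 response score kept its direction and an exact permutation p under 0.05 in every setting run, with differences from 0.70 (38 higher and 8 lower genes) to 1.77 in trabecular and from 0.73 to 1.78 in cortical bone. Every setting chose its score genes by the main fit on all arrays of the other bone. Only the setting with the first 50 genes by p, which gave the lowest differences, used other genes. Leaving out a replicate gave 1.17 to 1.77 and 1.33 to 1.78, with the score genes still chosen on all arrays. Median scaling was not run for the score. Of the named genes called, 3525 values over the alternatives kept the call and 502 lost it, and 0 turned direction. Of those not called, 21 values passed in an alternative, among them Sost in wild-type cortical bone with all 40 arrays (0.0178) and Myl10 in AF-1-deleted cortical bone after median scaling (0.0193). The counts of 0 for the genotypes in vehicle-treated bone stayed 0 in every setting. Where a cause is not given, the cause was not tested.

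E2 in wild-type trabecular bone (18 genes) gave 4 after median scaling, 47 with array quality weights, 10 at an adjusted p under 0.01, 42 without BeadChip 1 and with the block, and 13 with the muscle covariate (11 shared). Leaving out replicates gave 8 to 30: 30 without BeadChip 1, 9 without BeadChip 2, 8 without BeadChip 3 or 4, 11 and 10 without E2 replicates 4 and 5, and 10 without vehicle replicate 4. The 1 gene with the deletion became 0 with probes detected on all arrays, a filter that drops Myl10, and stayed 1 whichever replicate was left out. E2 in wild-type cortical bone (13 genes) gave 5 with probes detected on all arrays, 30 with all 40 arrays, 6 with its groups alone, 5 at 0.01, and 7 without BeadChip 1 and with the block. Leaving out replicates gave 3 to 12: 8, 8, 3 and 4 without BeadChips 1, 2, 3 and 4, and 5 and 8 without E2 replicates 3 and 4. With the deletion, 0 became 1 after median scaling, 1 with all 40 arrays, 1 with its groups alone and 48 with weights. Leaving out replicates gave 0 to 2: 2 without vehicle replicate 5 and 1 without BeadChip 5.

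The 1 gene differing by genotype in trabecular bone became 0 without background correction, with the authors' values, with probes detected on all arrays, with trend and robust empirical Bayes, and at 0.01. It became 2 with all 40 arrays, 5 with weights and 4 without BeadChip 1 and with the block. Leaving out replicates gave 0 to 3: 3 without BeadChip 1, 2 without AF-1-deleted E2 replicate 1, and 0 without BeadChips 2 to 5, wild-type E2 replicates 1 to 3, AF-1-deleted E2 replicates 2, 3 and 5, AF-1-deleted vehicle replicates 2 and 3, or wild-type vehicle replicate 2. In cortical bone 0 became 1 with all 40 arrays and 1 with weights, and leaving out replicates gave 0 to 1, with 1 without AF-1-deleted vehicle replicate 5 or BeadChip 5. The 1 gene differing in E2 effect between the bones became 0 without background correction, with the authors' values, after median scaling, with probes detected on all arrays, with its groups alone, with trend and robust empirical Bayes, with weights, at 0.01, and without BeadChip 1 and with the block. Leaving out replicates gave 0 to 1, with 0 without BeadChips 1, 3, 4 or 5, E2 replicates 3 or 5 of either bone, trabecular vehicle replicates 2 or 4, or cortical vehicle replicates 1 or 3. The 1950 genes between the bones became 718 after median scaling (709 shared, 91 higher and 627 lower), 1019 at 0.01 and 3256 (1751 higher and 1505 lower) without BeadChip 1 and with the block. Leaving out replicates gave 866 to 2640: 866, 1295 and 1297 without BeadChips 4, 2 and 5, and 1262 without cortical vehicle replicate 4.

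Of the lists, 7 in wild-type trabecular bone became 3 with an estimated and 13 with a preset correlation, 0 after median scaling, and 4 without BeadChip 1 and with the block. The 21 between the bones became 10 with an estimated correlation, 9 after median scaling, and 23 without BeadChip 1 and with the block (21 shared). With a preset correlation, the 0 elsewhere became 6 and 4 for E2 with the deletion in trabecular and cortical bone, 11 for E2 in wild-type cortical bone, 4 and 9 for the difference between genotypes in those bones, 4 and 6 for the genotypes with vehicle, and 6 for E2 between the bones. Without BeadChip 1 and with the block, 1 was called for the genotypes in trabecular bone. Fewer genes pass at 0.01 by construction. The block gave 16 genes for E2 in wild-type trabecular bone (14 shared) and 19 in cortical bone (13 shared). The replicate block alone changed no call of a named gene or list other than those given beside the results. Median scaling moved the median of all genes to 0.10 for E2 in wild-type cortical bone and −0.13 for E2 between the bones. Signal over background limits the dim genes: values without background correction were smaller, as for Shox2 (−0.76 against −2.00), and genes undetected in a group have only a bound.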

Other observations

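The tests of histone, S-phase and clock genes were chosen after those genes were seen, with lists written then. Histone genes stood out with E2 in wild-type cortical bone. Of 41 replication-dependent histone genes, which package newly made DNA, 33 had a positive difference with a median of 0.85, among them H2bc3 (1.47), H4c12 (1.43), H4c17 (1.37), H2bc15 (1.34) and H3c1 (1.29), and 25 had an unadjusted p under 0.05. Since the list was written after histones had been seen on these arrays, no p-value is given for it. Their median was 0.04 in wild-type trabecular and 0.05 in AF-1-deleted cortical bone. More cells in S phase would be a candidate explanation, but S-phase genes had a mean difference of −0.15 ± 0.39 (SD over 5 BeadChips) against 0.72 ± 0.21 for the histones. They lay below 0.5 of the histone shift by 0.51 with a standard error of 0.216, on 4 of 5 BeadChips. That more cells in S phase would move these genes by at least 0.5 of the histone shift was assumed. With that assumption and 5 BeadChips, the margin is too narrow to decide, and the explanation stays open. Release of histone transcripts that carry a poly(A) tail, or a difference in RNA handling, was not tested.

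In wild type of both bones the clock gene Arntl, whose transcript peaks opposite to the Per genes, had a positive difference with E2 and Per2, Dbp and Tef a negative one; over all genes Per2 was called in both bones and Arntl in cortical bone (trabecular adjusted p = 0.0987), and Nr1d1, of the Per phase, had 0.60 in cortical bone. The circadian list set beforehand was not called in cortical bone (fry adjusted p = 0.866), and in trabecular bone its call was lost with an estimated correlation (0.0964), after median scaling (0.981), and without BeadChip 1 and with the replicate block (0.154). A score of Arntl-phase minus Per-phase genes, chosen after the wild-type values were seen, which favours larger values there, was higher with E2 in wild type by 1.70 ± 0.52 in trabecular and 1.75 ± 0.29 in cortical bone (SD, n = 5 BeadChips). With the AF-1 deletion it was higher by 0.50 ± 0.29 (29.5% of wild type) and 1.32 ± 0.27 (75.7%). Collection of E2 and vehicle mice at different times of day cannot be told apart from an effect of E2 on these genes: the lower of the genotype differences was 0.42, and the labels give no time of collection.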
